A study of Mus musculus with 30 samples.

How the data were processed

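Kidney total RNA of 15 mice was measured on 2 array types, 30 samples in all, and groups and numbers were taken from the sample titles. The deposited intensity values are whole numbers per probe set, negative in 20.8% to 26.6% of the values of an array of the first table and 29.2% to 35.9% in the second. The software and background step behind them are not given in the sources used here. That the deposited intensities had been scaled follows from the values, since trimmed means of the arrays lay between 1474 and 1504.

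From these values each array was scaled to the common mean of its table after trimming 2% at each end, with factors of 0.997 to 1.01. A floor at the root mean square of the negative values, 1103 in the first table and 1815 in the second, was then applied and log2 taken. A probe set was tested if above the floor on at least 5 arrays of its table, which left 2609 and 1909. Values near the floor understate changes, and where a group lay at the floor on all its arrays the change is given as at least that fold. Left out were 122 control probe sets and 77 rows blank on young arrays, 16 of them not controls. Array annotation gave 7561 probe sets 1 gene symbol, of which 7544 were updated by gene number with a RefSeq gene table of assembly GRCm38.p6, used for names only. No symbol was given for 4567 probe sets of the second table, which are not named here.

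Tables were normalized separately and stacked by group and number. For 112 genes named on both tables, the deviations of an animal on its 2 arrays correlated with a mean r of 0.385 across genes, against -0.0938 for other animals of the group, and 14 of 15 animals matched themselves best. All 3 groups were fitted together with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over both tables at 0.05. Gene lists, 33 fixed before the data were examined and 30 of them with at least 5 measured genes, were tested with camera at a preset correlation of 0.01, using the brightest probe set of each gene, and again with an estimated correlation. Of the lists tested, 8 with age and 5 with the diet had a median, mean and test that differed in sign, none among those that passed.

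Named genes followed a rule set before the data were examined: the 10 largest rises and falls per comparison, up to 4 members of each list, up to 10 genes opposite in both, and fixed kidney markers and genes of other tissues. Because exchanged rows took some of these places, the rule was applied again without them. Kl, Angptl4, Cyp4a10, Sgk1, Prom1, Defb1, Acta2, Tpm1 and the leukocyte genes Ptprc and Cd37 were named after their values were seen.

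On simulated data with known changes, for ageing 55.4% of log2 changes of 1 and 85.2% of log2 changes of 2 were recovered over 4281 probe sets, with 5.52% false calls among all calls. For the diet these were 60.7%, 85.2% and 5.30% over 4298 probe sets. A list shifted on purpose passed, and so did 1 other of the 30. Each simulated probe set varied independently, without the variation that probe sets share on the real arrays. The share of false calls may therefore not hold for the real data. Probe sets constant over the arrays in a fit were given a change of 0 and a p of 1, a handling added after the alternative without a filter was first seen, where rounding had made such rows pass. Alternatives were quantile normalization, no further scaling, the floor doubled or halved, an asinh transform, other filters, trend and robust moderation, no moderation, separate fits, a replicate block and leaving out each animal. Added after seeing the data were leaving out the exchanged class, the number set as a term, and each set alone. Figures were drawn with matplotlib 3.10.9.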

Results

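Kidney total RNA of C57BL/6 mice, an inbred laboratory strain, was measured on 1-colour short-oligonucleotide arrays in 3 groups of 5 animals: control-fed mice of 5 months, control-fed mice of 30 months, and calorie-restricted mice of 30 months. Calorie restriction is a lowered food intake. Each animal was measured on 2 array types, which gave 30 samples, and the titles tie the arrays of an animal together by group and number. The first table held 6584 probe sets and the second 6595. Between 33.5% and 37.5% of the values of an array of the first table lay above the background floor, and between 24.0% and 27.8% in the second. Arrays of 1 group correlated with r of 0.868 to 0.970 across tested probe sets, which are not independent replicates. The labels name 2 comparisons, old against young controls for ageing and calorie-restricted against old controls for the diet. The labels do not state whether the 5 numbers of a group are separate animals. They are called animals here, and the p-values of single probe sets rest on the spread between these samples. The p-values of lists set the genes of a list against the other genes, and depend on the correlation between genes that is assumed or estimated. The number of arrays limits the precision.

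In the second table the young columns differed from the others in how values lie in rows. For targets with several probe sets marked by the suffixes i, f, s or r, 25 of 25 measured pairs changed order between young and old controls, and 0 of 24 did so between calorie-restricted and old controls. Measured means a log2 difference above 1 in both groups. Pairs of the same suffixes on the other array type changed order in 0 of 6 cases, and pairs with the suffixes at and g there in 0 of 33. An example is Klk1b5, a kallikrein, whose f probe set read -471.4 ± 119.7 (SD, n = 5) in young controls and 34540 ± 3878 in old controls, while its i probe set read 66440 ± 14650 and -527.2 ± 158.5. All 85 tested probe sets of this class in the second table are therefore set apart below, a choice made after the data were seen. No age change is read from Klk1b5, Klk1b26, Mcrip1, Hspg2 or Serpina1a. In the rest of the second table only 2 pairs, with the suffixes at and g, could be checked, and 0 changed order. The order of young values in its other rows was not checked. This limits the age changes read from them below, among them those of Ighm, Cd74, H2-Ab1, Mgp and Nnt.

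**Figure D1:**
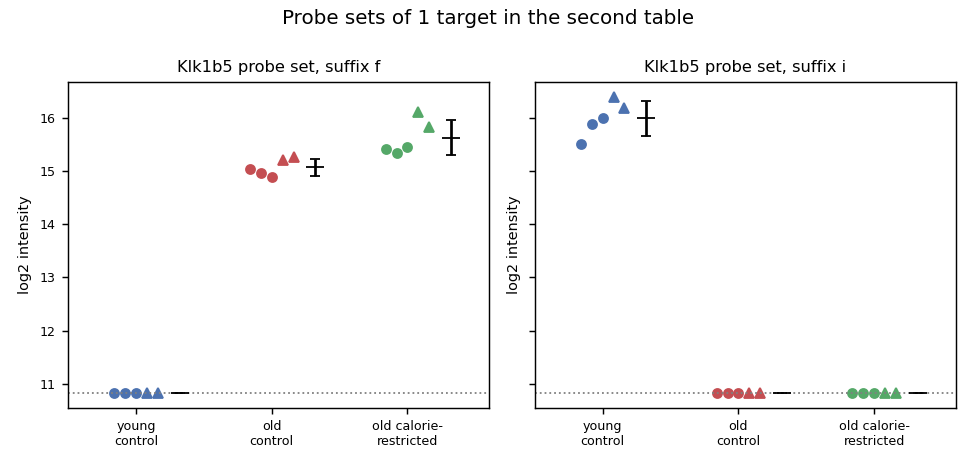
Log2 intensity of the f and i probe sets of Klk1b5 in each animal; circles are title numbers 1 to 3, triangles numbers 4 and 5, bars the mean and SD of 5 animals, and the dotted line the floor. Young controls lie at 10.83 for the f probe set and between 15.51 and 16.39 for the i probe set, and both old groups show the opposite order.

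Kidneys of old controls held more immunoglobulin RNA than those of young controls. Igha (probe set d11468_s_at), the heavy chain of IgA, rose by 4.54 ± 0.48 on the log2 scale (SE, n = 5 per group, adjusted p = 5.72e-06), from an intensity of 1751 ± 1431 (SD) to 41010 ± 10440. Ighm (X03690_s_at), the heavy chain of IgM, rose by 3.66 ± 0.36 and Jchain (j00544_s_at), which joins IgA and IgM chains, was at least 7.35-fold higher, since all 5 young controls lay at the floor. The class II antigen-presentation genes Cd74 (X00496_s_at) and H2-Ab1 (v01527_s_at) rose by 1.77 ± 0.16 and 2.04 ± 0.25, and the lysosomal protease Ctss (aa255186_s_at) by 1.61 ± 0.17. Among genes that fell were Nnt (Z49204_s_at), the mitochondrial transhydrogenase (-1.58 ± 0.24, adjusted p = 0.000305), Odc1 (s64539_s_at), the first enzyme of polyamine synthesis (-1.04 ± 0.14), and Klk1 (d10464_f_at), a renal kallikrein (-1.01 ± 0.19).

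Of the 8 measured genes of the B cell and plasma cell list, 4 rose, all over the tested probe sets and also when adjusted over the list alone, with a list median of 0.82 (camera adjusted p = 8.65e-10). The MHC and interferon list had 6 of 14 members up, 7 adjusted over the list alone, with H2-Eb1 at 1.43 ± 0.23 and Ly6e at 1.22 ± 0.26. In the macrophage and myeloid list 5 of 13 rose and 7 did so adjusted over the list alone, where 1 also fell. Lyz2, lysozyme, rose by 1.67 ± 0.30 and Laptm5 by 0.87 ± 0.20. The smooth muscle gene Tagln also rose (0.74 ± 0.17). Matrix genes rose as a list too (median 0.42, adjusted p = 1.15e-08). Of its 18 members 5 passed, 8 adjusted over the list alone, with Mgp, an inhibitor of calcification, at 1.53 ± 0.22, Bgn at 1.21 ± 0.29 and Dcn at 0.83 ± 0.21; Hspg2 is 1 of the 5 and stands among the exchanged rows. In the complement and acute phase list 2 of 6 rose, 3 adjusted over the list alone, namely Cp (1.07 ± 0.20) and Serping1 (0.80 ± 0.14) over all probe sets. These 5 lists also passed with an estimated correlation, with the highest adjusted p at 0.0185. In numbers 1 to 3 and in numbers 4 and 5, the medians were 0.92 and 1.04 for the B cell and plasma cell list, 0.44 and 0.85 for the MHC and interferon list, 0.52 and 0.63 for the macrophage and myeloid list, 0.50 and 0.37 for the matrix list, and 0.51 and 0.65 for the complement list. Ly6e read 0.78 and 1.88 in these sets, and H2-Eb1 1.01 and 2.06.

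The tubular injury list was higher (2 of 13 members rose, 5 adjusted over the list alone), led by S100a6 (1.36 ± 0.27) and Anxa2 (0.95 ± 0.25), with adjusted p = 0.00125 and adjusted p = 0.0607 with an estimated correlation. Oxidative phosphorylation genes were lower, with a median of -0.41 over 51 genes and an adjusted p = 4.19e-12, but adjusted p = 0.110 with an estimated correlation. Of them 2 fell, Cycs (-0.77 ± 0.21) and Ndufb3 (-0.58 ± 0.14), and 11 fell adjusted over the list alone. The oxidative phosphorylation medians in numbers 1 to 3 and in numbers 4 and 5 were -0.35 and -0.41, against 0.39 and 0.20 for tubular injury, -0.29 and -0.08 for the loop, distal tubule and collecting duct list, and -0.25 and -0.35 for the androgen-regulated list. In the loop, distal tubule and collecting duct list 4 of 12 fell by either adjustment, Klk1, the calcium-binding proteins Calb1 (-0.67 ± 0.17) and S100g (-0.66 ± 0.18), and Egf (-0.39 ± 0.11). Its test gave adjusted p = 0.0218 and adjusted p = 0.0607 with an estimated correlation. The androgen-regulated kidney list had 2 of 10 down, Odc1 and Hsd17b11 (-1.01 ± 0.18), with adjusted p = 0.00273 and adjusted p = 0.0725 with an estimated correlation.

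Other genes that fell with age were Inmt (-1.30 ± 0.29), C1qtnf3 (-1.25 ± 0.22), Acat1 (-1.10 ± 0.24), Coasy (-1.09 ± 0.23), Hsd11b1 (-1.07 ± 0.26), which regenerates active glucocorticoid, Amacr (-1.06 ± 0.17), Lpl (-0.92 ± 0.17) and Gatm (-0.87 ± 0.16), which makes the precursor of creatine. Cx3cl1, a chemokine, rose by 1.53 ± 0.15, Hspb1, a small heat shock protein, by 1.07 ± 0.21, and Aldh1a1 by 1.07 ± 0.16. In the cholesterol and fatty acid synthesis list, which did not pass (adjusted p = 0.522), Idi1 fell by 0.66 ± 0.12 and Hmgcs1 by 0.52 ± 0.14. The age calls of S100g, Egf, Hmgcs1 and Cycs were lost in 22, 20, 20 and 17 of 32 alternatives. The kidney markers Slc34a1 (-0.05 ± 0.12), Umod (0.22 ± 0.21) and Kap (-0.30 ± 0.35) did not pass. Ren1 was not analysed here, and Igf1 did not pass the filter.

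**Figure D2:**
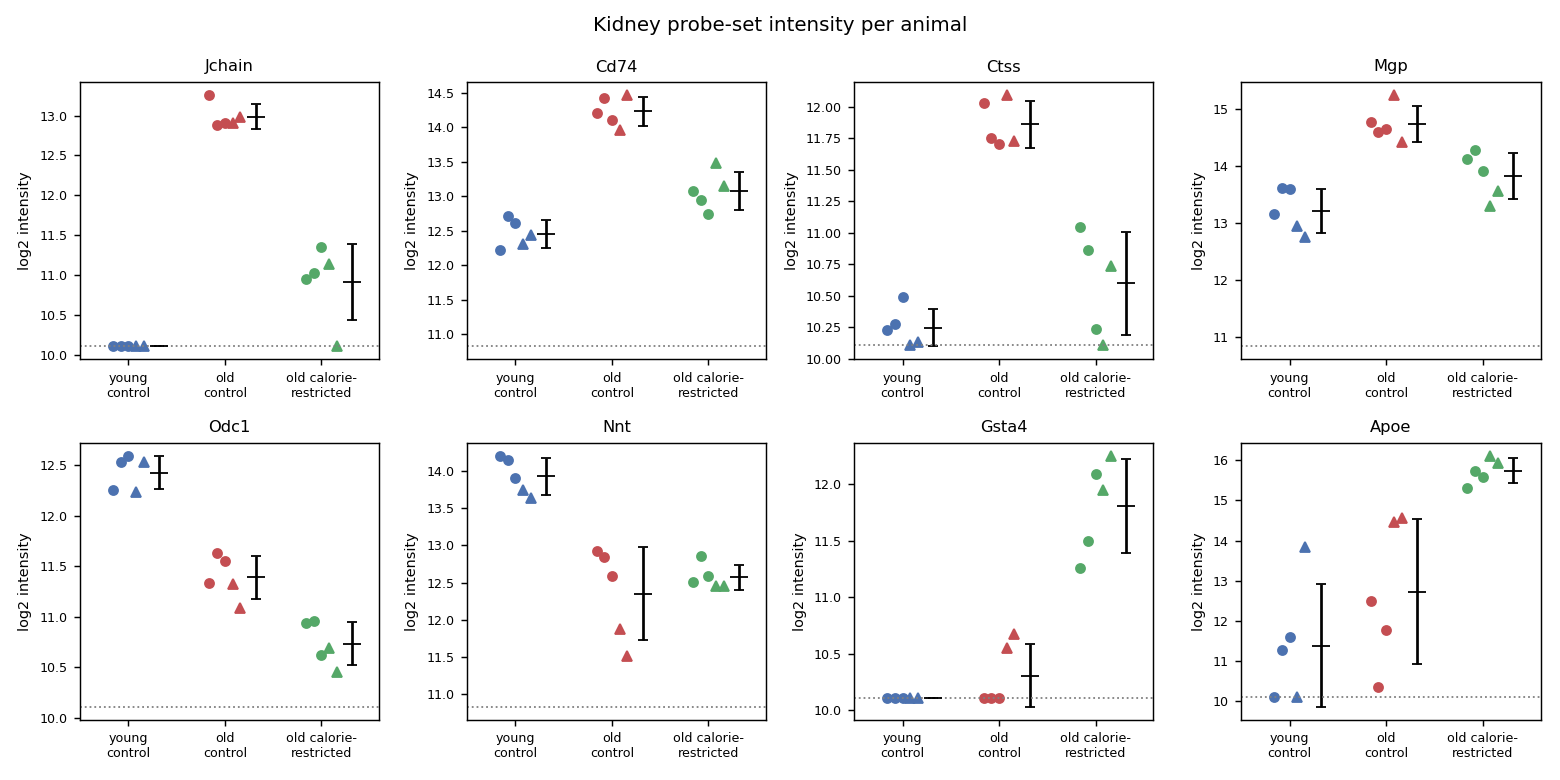
Log2 intensity per animal for 8 genes by group; circles are title numbers 1 to 3, triangles numbers 4 and 5, bars the mean and SD of 5 animals, and the dotted line the floor. Cd74 lay between 13.96 and 14.47 in old controls against 12.22 to 12.72 in young controls, and Apoe between 15.31 and 16.11 under calorie restriction against 10.36 to 14.57 in old controls.

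In total 233 of 4518 probe sets changed with age, 135 higher and 98 lower, by limma with Benjamini-Hochberg adjustment, and 58 of these belonged to the exchanged class. Without that class 150 of 4433 changed, 96 higher and 54 lower, covering 44 named genes up and 35 down. Title numbers 1 to 3 and 4 and 5 form 2 sets that differ within every group. Igha changed by 4.18 and 5.09, Ighm by 2.83 and 4.89, and Cd74 by 1.73 and 1.84 in them. Outside the exchanged class, 85 passed in numbers 1 to 3 alone and 48 in numbers 4 and 5 alone, against 156 and 146 with it. With the number set as a term, 349 passed with the class and 253 without it. Limits are that the sets separate along the first component of within-group deviations, which held 37.0% of their variance, and that the labels do not record what they are.

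Calorie-restricted mice held less immunoglobulin and antigen-presentation RNA than old controls of the same age, and more RNA of single genes such as Gsta4 and Apoe. Ighm fell by 2.57 ± 0.36 on the log2 scale (SE, n = 5 per group, adjusted p = 0.000492), and Igha and Jchain also fell (-2.41 ± 0.48 and -2.07 ± 0.18). Among genes of antigen presentation and macrophages, Cd74 (-1.15 ± 0.16), H2-Aa (AF027865_2_s_at, -1.27 ± 0.18), Ctss (-1.26 ± 0.17) and C1qb (-1.15 ± 0.17), a complement component made by macrophages, fell. Gsta4 (aa638086_s_at), a glutathione transferase, rose 2.82-fold (adjusted p = 0.000174), with 3 of 5 old controls at the floor. Apoe (d00466_f_at), a lipoprotein component, rose 8.02-fold (adjusted p = 0.0444), from 11460 ± 11020 (SD) to 55420 ± 11680, and its probe set on the second table read 2.16 ± 0.61 (adjusted p = 0.0798). On the first table Apoe was 16-fold higher in numbers 1 to 3 and 2.85-fold in numbers 4 and 5, and its call was lost in 19 of 32 alternatives.

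In the B cell and plasma cell list 4 of 8 members fell, 6 adjusted over the list alone, with a median of -0.83 and a camera adjusted p = 2.96e-09. In the macrophage and myeloid list 2 of 13 fell, 5 adjusted over the list alone (median -0.39, adjusted p = 8.27e-06). In the matrix list Mgp alone of 18 members fell (-0.91 ± 0.22, with -0.57 in numbers 1 to 3 and -1.42 in numbers 4 and 5), 4 adjusted over the list alone, with a median of -0.23 and adjusted p = 0.00106. These 3 lists also passed with an estimated correlation, and their medians in numbers 1 to 3 and in numbers 4 and 5 were -0.95 and -0.65, -0.45 and -0.48, and -0.28 and -0.29. The matrix list did not pass in numbers 1 to 3 alone (adjusted p = 0.0725). In the MHC and interferon list 5 of 14 fell, 6 adjusted over the list alone, with Tapbp, which loads peptides on class I molecules, at -1.45 ± 0.30; its adjusted p = 4.59e-07 became adjusted p = 0.0568 with an estimated correlation, and its medians in the number sets were -0.55 and -0.71.

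The other 6 lists that passed were higher under calorie restriction, and none of these passed with an estimated correlation. Without calorie-restricted animal 5, fatty acid oxidation was the 1 list of these still past the threshold (adjusted p = 0.0162), and in numbers 1 to 3 alone ribosomal proteins were (adjusted p = 0.0114). Fatty acid oxidation and ketone synthesis had a median of 0.25 over 26 genes (adjusted p = 0.00135, adjusted p = 0.147 with an estimated correlation), with 1 gene past the threshold, Cyp4a14 (1.64 ± 0.41), and 7 adjusted over the list alone. Ribosomal protein genes had a median of 0.20 over 37 genes, 0 of which passed by either adjustment (adjusted p = 0.00655, adjusted p = 0.685 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.10 over 51, also with 0 by either adjustment (adjusted p = 0.0223, adjusted p = 0.685 with an estimated correlation). Amino acid metabolism had 2 of 22 up, 3 adjusted over the list alone, Hpd (1.45 ± 0.29) and Prodh2 (0.64 ± 0.16) over all probe sets, with adjusted p = 0.0317 and adjusted p = 0.0873 with an estimated correlation. In the loop, distal tubule and collecting duct list Egf rose by 0.45 ± 0.11, 3 members did so adjusted over the list alone, and adjusted p = 0.0387 became adjusted p = 0.112 with an estimated correlation. The renin, angiotensin and kallikrein list had 0 of 6 members past the threshold, 3 adjusted over the list alone, with adjusted p = 0.0192 and adjusted p = 0.231 with an estimated correlation. Without Klk1b5 and Klk1b26, which stand among the exchanged rows, it is too small to test. In numbers 1 to 3 and in numbers 4 and 5 the medians were 0.16 and 0.41 for fatty acid oxidation, 0.18 and 0.18 for ribosomal proteins, 0.10 and 0.20 for oxidative phosphorylation, 0.12 and 0.30 for amino acid metabolism, 0.17 and 0.26 for the loop and distal tubule list, and 0.24 and 0.70 for the renin and kallikrein list.

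**Figure D3:**
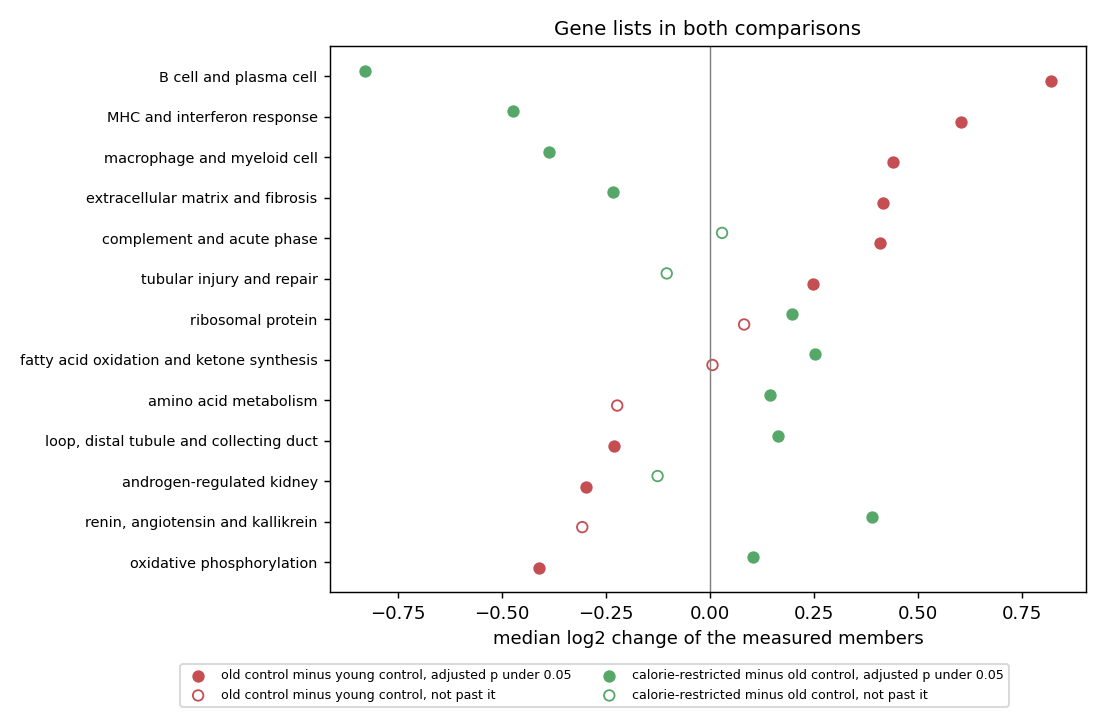
Median log2 change of the measured members of each gene list that passed in either comparison, for old minus young controls and for calorie-restricted minus old controls; filled points passed camera with the preset correlation. The B cell and plasma cell list lies at 0.82 with age and -0.83 with the diet.

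Among other genes, Cyp2d26 (1.32 ± 0.25), Hmox1, heme oxygenase (1.37 ± 0.34), Pxmp2 (1.34 ± 0.32), Id1 (1.13 ± 0.27), Tial1 (0.95 ± 0.24), Timm9 (0.75 ± 0.19) and Aldh1a1 (0.70 ± 0.16) rose with the diet. Psd (-1.34 ± 0.33), Gjb6 (-1.20 ± 0.22), Cndp2 (-0.75 ± 0.13) and Odc1 (-0.66 ± 0.14) fell. Some of these differed between numbers 1 to 3 and numbers 4 and 5, with 1.31 and 0.42 for Tial1, 0.98 and 0.40 for Timm9, -1.91 and -0.48 for Psd, and 0.87 and 2.13 for Hmox1. The calls were lost in 22 of 32 alternatives for Tial1, 23 of 32 for Timm9, 17 of 32 for Psd, 21 of 30 for Hmox1, 16 of 32 for Pxmp2, Cyp4a14 and Mgp, and 18 of 32 for Prodh2. Gsta4, Hmox1 and Aldh1a1 are the 3 of 37 members of the antioxidant and conjugation list that rose, and the list did not pass (adjusted p = 0.361). Aldh1a1 rose and Odc1 fell in both comparisons. The probe sets of Col1a1 disagreed, with 1.07 ± 0.24 for 1 that passed and -0.39 and 0.48 for 2 that did not. Lists of other tissues did not pass: with the diet the adjusted p was 0.671 for fat, 0.846 for adrenal, 0.204 for red blood cells and 0.913 for muscle. With age it was 0.983, 0.970, 0.547 and 0.430. The haemoglobin gene Hba-a1 read 0.74 ± 0.29 with age and -0.48 ± 0.29 with the diet, the fat hormone Adipoq 0.51 ± 0.27 and -0.35 ± 0.27, the adrenal factor Nr5a1 0.34 ± 0.18 and -0.27 ± 0.18, and the muscle kinase Ckm -0.66 ± 0.26 and 0.49 ± 0.26, none of them passing over all probe sets. Of the muscle list the smooth muscle gene Tagln rose with age (0.74 ± 0.17, adjusted p = 0.0117), and adjusted over the list alone Acta2 (0.66) and Tpm1 (0.47) also rose and Ckm fell. Of the adrenal list Fdx1 fell with age (-0.89 ± 0.18, adjusted p = 0.00414), and of the fat list Lpl.

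In total 118 of 4518 probe sets changed with the diet, 41 higher and 77 lower, and 112 of 4433 without the exchanged class. Ighm changed by -2.04 in numbers 1 to 3 and -3.35 in numbers 4 and 5. Gsta4 changed by at least 1.51 in numbers 1 to 3, where the old controls lay at the floor, and by 1.49 in numbers 4 and 5. With the number set as a term, an alternative chosen after seeing the data, the count was 224, and it was 253 among numbers 1 to 3 and 9 among numbers 4 and 5. Without calorie-restricted animal 1 it was 73 and without animal 5 it was 78.

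Both comparisons contain the old controls. Of all 233 probe sets that changed with age, 159 (68.2%) moved the opposite way with the diet. Simulated groups gave 89.0% (83.7% to 93.6%) with no effect and 65.7% (62.1% to 70.6%) with an age effect and no diet effect. Of the 150 probe sets that changed with age outside the exchanged class, 122 (81.3%, exact 95% interval 74.2% to 87.2%) moved the opposite way with the diet. Simulated groups with no effect gave 89.7% for as many top probe sets, because the old controls are shared, with a range of 83.3% to 95.3%. A simulated age effect with no diet effect gave 67.7% (61.7% to 72.6%). The share outside the exchanged class lay below the simulation without effects and above the one with an age effect alone. The share of all 233 lay within the range of the latter. In the simulations each probe set varied independently, whereas the first component held 37.0% of the variance of the real within-group deviations. The simulated ranges and the exact interval leave out this shared variation, so they are too narrow to decide between these cases. In numbers 1 to 3 alone the share of all that changed was 59.0% and in numbers 4 and 5 alone 74%, and the simulations were not run by number set. With the old controls split into 2 and 3, the share outside the exchanged class had a median of 74.7% over 20 splits and ranged from 53.9% to 95.4%. Over all probe sets the median was 60.3%, with a range of 44% to 67.9%. The simulations were not split in this way. Outside the exchanged class the covariance of the log2 changes was -0.0714 against -0.0292 simulated without effects, a difference of -0.0422, with a correlation of -0.489 against -0.498. Over all probe sets the correlation was -0.376 against -0.499. Higher with age and lower with the diet were 55 probe sets of 96 and 72, against 1.56 if the lists were independent, which they are not. Another 2 were lower with age and higher with the diet, against 0.487.

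Over all tested probe sets, 18 named genes passed in both comparisons with opposite signs, 16 up with age and down with the diet and 2, Defb1 and Egf, the reverse. Defb1, an epithelial defensin, changed by -0.68 ± 0.17 with age and 0.70 ± 0.17 with the diet. Cx3cl1 changed by 1.53 ± 0.15 and -0.79 ± 0.15. Tmsb10 was at least 1.78-fold higher with age, with all 5 young controls at the floor, and changed by -0.83 ± 0.13 with the diet. Lgals3bp rose by 0.89 ± 0.17 with age and was at least 1.91-fold lower with the diet, with all 5 calorie-restricted animals at the floor.

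Calorie-restricted mice also differed from young controls, a comparison the labels do not name. Apoe was higher by 4.35 ± 0.76 on the first table and 4.33 ± 0.61 on the second, Cyp4a14 was 6.06-fold higher (adjusted p = 0.000676), and Odc1 lower at -1.69 ± 0.14. On the log2 scale Cyp4a14 was higher by 3.09 in numbers 1 to 3 and by 1.865 in numbers 4 and 5. Igha stayed above the young level (2.14 ± 0.48, adjusted p = 0.0118), as did Cd74 (0.62 ± 0.16) and Jchain (at least 1.75-fold, adjusted p = 0.0121). Ighm (X03690_s_at, 1.09 ± 0.36), H2-Ab1 (0.82 ± 0.25), H2-Aa (0.28 ± 0.18) and Ctss (0.35 ± 0.17) did not pass against young controls. Nor did the B cell and plasma cell list (2 of 8 higher, camera adjusted p = 0.194), the MHC and interferon list (1 of 14, adjusted p = 0.242) or the macrophage and myeloid list (0 of 13, adjusted p = 0.921). In all 258 probe sets passed, and 169 without the exchanged class, 88 higher and 81 lower. With the number set as a term 439 passed, and 341 without the exchanged class. In numbers 1 to 3 alone 324 passed and 237 without that class, and in numbers 4 and 5 alone 104 and 13. Of the lists 6 passed and 0 did so with an estimated correlation. Lower were the androgen-regulated kidney list (median -0.35, adjusted p = 9.48e-05, adjusted p = 0.0780 with an estimated correlation) and oxidative phosphorylation (median -0.24, adjusted p = 9.48e-05, adjusted p = 0.612 with an estimated correlation). Higher were complement and acute phase (adjusted p = 0.00537, adjusted p = 0.0780 with an estimated correlation), ribosomal proteins (adjusted p = 0.00166, adjusted p = 0.690 with an estimated correlation), immediate early genes (adjusted p = 0.00375, adjusted p = 0.130 with an estimated correlation) and fatty acid oxidation (adjusted p = 0.0150, adjusted p = 0.344 with an estimated correlation).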

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

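The tests of the exchanged rows, of the immune lists within each number set, of tubule share, of leukocyte genes and of Apoe were chosen after the results were seen. Of 297 groups of 5 animals checked for 1 animal far from the rest, 21 stood out, and chance gives about 1 in 20 groups, here 14.8. The gap of the farthest animal, as a share of the range of its group, is given for each. In young controls it was 1 for Cidea in animal 1, 1 for Hsd3b1 in animal 2, 0.79 for Col1a1 and 0.794 for Tial1 in animal 4, 0.863 for Lgals3bp in animal 5 and 0.715 for Prodh2 in animal 2. In old controls it was 0.791 for Col1a1 and 0.792 for Pxmp2 in animal 4, 0.841 for Dgat2 in animal 5, 0.843 for Hsd3b1 in animal 3, 1 for Idi1 in animal 1, 0.773 for Inmt in animal 2, 0.723 for Jchain in animal 1 and 1 for Klk1b26 in animal 3. In calorie-restricted animals it was 1 for Cidea and 0.73 for Gatm in animal 5, 0.711 for Ckm, 0.756 for Gjb6 and 1 for Tmsb10 in animal 4, 0.727 for Hspg2 in animal 1 and 0.792 for Id1 in animal 3. A share of 1 is an animal above the floor with the other 4 at it.

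Opposed age shifts of probe sets of 1 target were found in the second table. Of the measured pairs, 100% changed order between young and old controls, as values standing exchanged between rows of the young columns would give. A true change of transcript forms with age is argued against by 0% of such pairs in the first table, where 6 were measured and the exact 95% interval reaches 45.9%. How the exchange arose was not tested.

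Immune genes were higher in old controls and lower under calorie restriction. Without any 1 animal at least 86.7% of the called members of the B cell, MHC and macrophage lists stayed past the threshold. This argues against 1 animal. Every group holds the same title numbers, so the number set by itself cannot make a difference between groups. All 12 camera tests of these lists for age and diet in each number set by itself passed with the preset correlation (adjusted p from 2.51e-10 to 0.0301). Over all animals the MHC list with the diet has adjusted p = 0.0568 with an estimated correlation. The 100% of called members with the same sign in both sets is nearly fixed by their choice. A lower share of tubule cells in old controls, as the whole of the change or as part of it, cannot be told apart. The 30 immune, endothelium and muscle genes above the floor did not move alike (SD of their log2 changes 2.67 times their SE, 95% bootstrap interval 1.95 to 3.27). Genes that tubule cells also express would rise less and give such a spread too, and whether these genes are so expressed was not tested. The immune lists exceeded the endothelium and muscle lists by 0.45 (-0.08 to 0.82). More leukocytes may be present. Of 6 measured pan-leukocyte genes, 3 were also in the macrophage list. The median of the 6 was 0.30 (0.15 to 0.70) with age and -0.60 (-0.80 to -0.08) with the diet. Only Laptm5 passed with age and only Cd37 with the diet. Ptprc, found in all leukocytes, read 0.22 with age (adjusted p = 0.550) and -0.001 with the diet (adjusted p = 1). Ptprc thus gave no sign of fewer leukocytes under the diet, though 1 gene cannot decide this. The intervals in this paragraph come from resampling genes, not animals, so they leave out the spread between animals. The differences between the groups were tested above, and age and diet as their cause stay open.

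Apoe was higher under calorie restriction than in both control groups. It also read higher in old than in young controls. The rise was 2.17 ± 0.61 on the second table (adjusted p = 0.0497, a call lost in 22 of 32 alternatives) and 1.34 ± 0.76 on the first (adjusted p = 0.411). A defect of 1 table is argued against by Pearson's r of 0.926 between the tables over 15 animals (permutation p = 1e-05, the smallest the draws allow, Spearman's rho 0.957, permutation p = 1e-05), 0.889 without the 2 animals farthest from the median and 0.806 within groups. The number set by itself cannot make the difference, since every group holds the same numbers. Within each set on both tables, the lowest calorie-restricted value lay above the highest old control value by at least 1.26 on the log2 scale. On the first table old controls lay at 10.36 to 12.49 in numbers 1 to 3 and at 14.45 to 14.57 in numbers 4 and 5, and the difference was 16-fold and 2.85-fold. Binding of another transcript cannot be told apart, because 0 probe sets with unique probes were measured. The difference between the diets was tested above, and the diet as its cause stays open.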

How the results depend on the processing

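The alternatives without the exchanged class, with the number set and within each set were chosen after seeing the data. Single genes and lists were run under alternatives for the comparisons that the labels name, not for calorie-restricted against young mice. All 64 named probe sets called with age and all 35 called with the diet kept their sign in every alternative in which they were tested; 24 and 0 of them stayed past the threshold throughout. Of the probe sets that differed between calorie-restricted and young mice, 133 were higher and 125 lower, and 126 and 130 with quantile normalization. For counts of probe sets, the diet count of 118 became 68 with no filter, where 6991 of 13041 rows lie at the floor on all arrays and count as unchanged, 50 with a filter of 10 arrays, and 72 with only the groups compared. The number set as a term gave 349 with age, 224 with the diet and 439 between calorie-restricted and young mice, and 253, 217 and 341 without the exchanged class. Numbers 1 to 3 alone gave 253 with the diet, and numbers 4 and 5 alone gave 146 with age, 9 with the diet and 104 for calorie-restricted against young mice, or 48, 9 and 13 without the exchanged class. Without the exchanged class the count was 150 with age and 169 for calorie-restricted against young mice. The opposite share of 68.2% became 81.3% without the exchanged class, 76.3% with the number set as well, 59.0% in numbers 1 to 3 and 74% in numbers 4 and 5. Lists passing with an estimated correlation were 5 with age and 3 with the diet. With the preset correlation, 4 lists passed with the diet in numbers 1 to 3 alone. Fewer probe sets or samples enter some of these by construction, and otherwise the cause was not tested. Lists were not run by table or without moderation.

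Leaving out each animal in turn gave 179 to 254 probe sets with age, 73 to 133 with the diet, 195 to 266 for calorie-restricted against young mice, an opposite share of 65.2% to 71.2%, and 8 to 10 and 5 to 11 lists. The 5 was without calorie-restricted animal 5, with 1 higher and 4 lower, against 6 and 4. With the title number as a replicate block the counts were 277, 170 and 325, the share 66.1%, and 9 and 9 lists. The labels do not say that numbers pair animals, same-number deviations correlated from -0.0149 to 0.489 with 13 of 15 pairs above 0.1, and the mean was 0.264 within a number set and -0.285 between sets. Of the animals, 2 of 15 animals matched their own number best. Signal near the floor limits dim genes.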

Other observations

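The genes of this paragraph and the splits without the exchanged class or with the number set were chosen after the results were seen. Single genes were higher in calorie-restricted than in young mice, among them Angptl4 by 1.55 ± 0.26 (adjusted p = 0.000967), Cyp4a10 by 1.63 ± 0.25 and Vnn1 by 1.67 ± 0.26, while Lpl (-1.21 ± 0.17) and Hmgcs1 (-0.74 ± 0.14) were lower. Sgk1, a kinase of sodium transport, was higher by 1.46 ± 0.30 and Prom1 by 1.35 ± 0.18. Kl, which encodes klotho, a protein of phosphate balance, was lower in old than in young controls by both of its probe sets (-0.95 ± 0.16, adjusted p = 0.000962, and -0.73 ± 0.19) and changed by 0.11 and 0.02 with the diet without passing. Nnt, part of which is deleted in the C57BL/6J substrain, was lower in both old groups, with intensities of 15750 ± 2670 (SD, n = 5) in young controls, 5588 ± 2161 in old controls and 6115 ± 748.9 under calorie restriction. Its probe set stands in the second table outside the exchanged class. As for other rows there, the order of its young values was not checked.

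Other splits of the animals were drawn 100 at a time, the real one included. For age, 2 of 100 gave as many probe sets as the real 233, with 243 as the highest other, and without the exchanged class 3 of 100 gave as many as 150, with 183 as the highest. Those larger splits follow the number sets, with 5 of 6 animals of numbers 1 to 3 on one side, although other splits of that kind gave as few as 3, which points to a structure of the samples. With the number set as a term and without the exchanged class, 1 of 100 reached the real 253 and the highest other gave 22. That 1 is the real split itself, so 1 of 100 is the smallest share this test could give. The real groups hold the number sets in equal shares, and other splits need not. The term then costs those splits precision, so chance is less likely but not excluded. For the diet 1 of 100 reached 118 probe sets (highest other 31). For calorie-restricted against young mice 1 of 100 reached 258 (highest other 1), of which 58 belonged to the exchanged class. Without that class 1 of 100 reached 169 (highest other 2). Chance is less likely for these counts too, at the smallest share that the test could give. Chance cannot be excluded for the number of lists with age, where 9 of 100 splits gave as many as 9 (highest other 12), or 10 of 100 as many as 10 with the number set as a term and without the exchanged class (highest other 12). For the diet 2 of 100 gave as many as 10 lists, since 1 other split tied the real count (highest other 10). Chance is thus less likely there but not excluded, and the count depends on the preset correlation.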
